A study of Mus musculus with 6 samples.

How the data were processed

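Total RNA from single mouse embryos at embryonic day 8.5, 3 wild type and 3 heterozygous for Tcof1, was amplified and biotin-labelled from 100 ng in 2 cycles, and 20 µg of cRNA from each embryo was hybridised to a separate Affymetrix Mouse Genome 430 2.0 array, per the labels' protocols. Genotype and replicate number were taken from the sample titles. The authors deposited 1 linear intensity per probe set and array, made with GCOS, the scanner software, per the submitters' processing notes; its version and the signal algorithm are not given in the sources used here. The deposited intensities had a 2% trimmed mean of 150 on every array, found from the values, which removes differences in overall brightness before any comparison. Instrument records per array, which hold no expression values, were read for the scan day and fluidics module per the file headers. On the first day 4 arrays were scanned, replicates 1 and 2 of both genotypes, and on the second 2 arrays, replicate 3 of both. Wild-type replicates 1, 2 and 3 were on fluidics modules 1, 3 and 1, and heterozygous replicates 1, 2 and 3 on modules 2, 4 and 2. No module held both genotypes, so module cannot be told apart from genotype. Detection calls and probe-level images were not used here, so background was judged from bacterial control probe sets without a spiked target, whose highest signal was 8.55 to 13.5 per array.

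The file held 45101 probe sets, of which 64 Affymetrix controls were left out. Values were transformed to log2(signal + 1.87), where 1.87 is the 10th percentile of all values that were not controls. The 40% of probe sets with the lowest mean, which lay below a signal of about 13.2, were left out, and 27022 were tested. The authors' scaling was kept. Differences were fitted with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment at 0.05 over all tested probe sets, and genotype as the sole term. Fold changes are on this log2 scale. Probe sets were named from the platform annotation, with symbols updated by gene identifier through the NCBI RefSeq gene table of GRCm38.p6, which changed 0 symbols. Of the probe sets, 34945 had 1 symbol, 932 had several and were not named, and 9160 had none.

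The genes named were fixed before the data were examined: Tcof1; 5 genes recalled from the study (Ccng1, Trp53inp1, Pmaip1, Perp and Zmat3); the 12 genes higher and the 12 genes lower with the smallest p, 1 probe set per gene, whether or not they passed; and the 2 members with the smallest p of each gene list, on the probe set with the highest mean. Sex-linked and quality control genes are named as such. Genes named outside this rule are said to be chosen after their values were seen. The 30 gene lists, with 870 genes of which 780 were matched to a symbol on the array, were also fixed beforehand and covered p53 targets, nucleolar and ribosomal functions, tissues of the embryo, extraembryonic and maternal tissue, cell cycle, stress and metabolism. Lists were tested with camera on 1 probe set per gene, with a preset correlation of 0.01 and adjustment over the 30 lists, and counts of members were also adjusted over each list alone. Measures per array were compared with exact permutation tests, for which 10 splits of 6 arrays exist and 0.1 is the smallest two-sided p. Figures were drawn with matplotlib 3.10.9.

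The fit was tested on simulated data in 5 runs. Log2 values were drawn with the spread of these arrays, and probe sets were changed by known folds. False calls made up 4.69% of calls, and a run with no change gave 0. The set test was tried on simulated data with 1 list shifted by 0.5 on the log2 scale, and only that list passed camera. That outcome does not show whether the preset correlation suits the lists of these embryos. Alternatives were another pseudocount (1, or the 25th percentile, 7.03), quantile normalization, equal array medians, no filter or a filter at 60%, a variance prior without the trend, array weights, the replicate number as a block, scan day as a block, sex-linked genes left out, each array left out in turn, and for lists an estimated correlation or the mean of all probe sets of a gene. Xist signal as a covariate and the first scan day alone were added after seeing the data, as was scan day as a block for the lists.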

Results

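Gene expression was measured in whole mouse embryos at embryonic day 8.5, a stage at which the neural folds are closing and cranial neural crest cells are leaving them. The embryos were 3 wild types and 3 littermates with 1 working copy of Tcof1, the gene that encodes treacle, a nucleolar protein needed for ribosomal RNA synthesis; loss of 1 copy of the human gene causes Treacher Collins syndrome. Each embryo was hybridised to its own Affymetrix Mouse Genome 430 2.0 array, on which a probe set is a group of short oligonucleotides that together give 1 signal for a transcript. The deposited values were linear signals in arbitrary units, with the trimmed mean of every array at 150 and array medians between 21.0 and 25.6. Array pairs correlated between 0.964 and 0.974 on the log2 scale, and no pair held the same values. The number of arrays, 3 per genotype, limits the precision of every comparison. Of the 45037 probe sets that were not controls, the 27022 brightest were tested, and they covered 12857 named genes.

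The first question was whether the transcript of the targeted gene was reduced in the heterozygotes. Tcof1 signal on its brightest probe set was 387 ± 5.89 (SD, n = 3) in wild-type embryos and 211 ± 27.7 (SD, n = 3) in heterozygotes, so that heterozygotes carried 54.5% of the wild-type signal. All 3 heterozygotes, at 179 to 231, lay below all 3 wild types, at 382 to 393. The other probe sets of the gene gave 60.9% and 64.9% of the wild-type signal. In the limma fit the log2 difference was -0.88 with a standard error of 0.12 and an adjusted p of 0.0352 for the brightest probe set, which was the single probe set called lower in the heterozygotes. The other probe sets differed by -0.70 (adjusted p = 0.385) and -0.61 (adjusted p = 0.582) and did not pass. The difference was -0.95 among the 4 arrays of the first scan day and -0.74 among the 2 arrays of the second scan day. The call was lost whenever any 1 array was left out (limma adjusted p from 0.0575 to 0.192) and with scan day as a block (adjusted p = 0.0906). It was also lost without the intensity trend (0.413), with the replicate number as a block (0.182), with Xist signal as a covariate (0.143) and on the first scan day alone (0.217), and it passed in 8 of 19 alternatives. Where the probe sets lie relative to the altered part of the allele is not given in the sources used here, so the signals measure transcript level and do not check the allele itself.

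Heterozygous embryos had higher levels of a small group of genes, 12 of the 15 with a name in lists of known targets of the transcription factor p53. Of these 12, 5 were recalled from the study of these same embryos and so are not independent evidence. The other 7 were in a separate list of p53 targets. Ccng1, which encodes cyclin G1, rose 5.69-fold, from a signal of 492 ± 8.27 to 2840 ± 564 (SD, n = 3 per genotype). Cdkn1a, the gene of the cyclin-dependent kinase inhibitor p21, rose 8.76-fold, from 72.0 ± 16.3 to 662 ± 243, and Eda2r, a receptor for ectodysplasin A2, rose 6.14-fold, from 29.6 ± 5.93 to 195 ± 59.7. Trp53inp1, a p53-induced nuclear protein, rose 4.42-fold, from 206 ± 15.5 to 931 ± 204. These folds were computed on the log2(signal + 1.87) scale and understate the change of dim genes.

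In all, 22 of 27022 probe sets passed in limma at an adjusted p under 0.05, of which 21 were higher in heterozygotes and stood for 15 named genes and 1 probe set without a gene name. Every one of the 22 separated the genotypes without overlap. Across all tested probe sets, 3289 (12.2%) did so, where chance gives 10%. At an unadjusted p under 0.05, 814 probe sets were higher and 867 lower, a total of 1681 where chance gives 1351. The false splits of the same arrays gave 766 to 1654 such probe sets. The highest of these lay near 1681, so the excess over 1351 cannot be put down to genotype. Simulated changes in 27022 probe sets with the spread of these arrays were recovered in 18% of cases at 1.5-fold, 34.4% at 2-fold, 62.8% at 3-fold and 71.6% at 4-fold, so that many changes of modest size would have been missed. The median size of the 22 differences was 108% of the pooled difference on the first scan day and 84.6% on the second, and 14 passed with scan day as a block. The count depended on the estimate of the variance: without the intensity trend in limma's prior, 0 probe sets passed (smallest adjusted p = 0.0555, 1571 at an unadjusted p under 0.05). Leaving out 1 array gave 8 to 20 calls, with 8 without wild-type embryo 1, 11 without wild-type embryo 2 or 3 and 12 without heterozygous embryo 2.

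**Figure D1:**
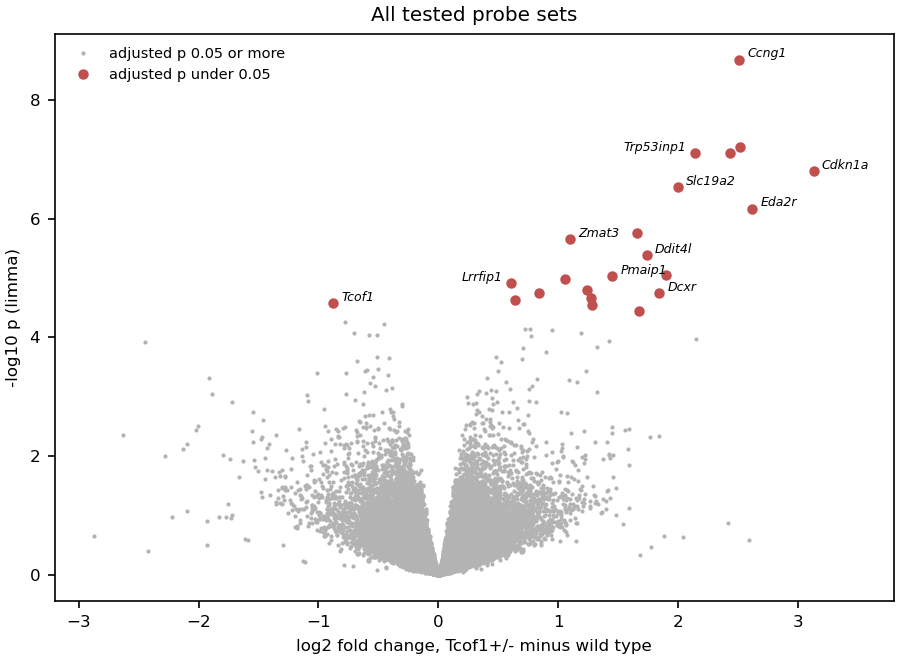
Each point is 1 of the 27022 tested probe sets, with the log2 fold change of heterozygous over wild-type embryos on the horizontal axis and minus log10 of the unadjusted limma p on the vertical axis. Red points are the 22 probe sets past an adjusted p of 0.05: 21 lie to the right (higher in heterozygotes) and 1, for Tcof1, to the left.

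The 5 p53 target genes recalled from the study of these embryos were all higher in heterozygotes. Besides Ccng1 (log2 2.51, SE 0.12) and Trp53inp1 (2.14, SE 0.15), these were Pmaip1, which encodes the pro-apoptotic BH3 protein Noxa (1.45, SE 0.17), Perp, a p53 effector in the plasma membrane (1.28, SE 0.17), and Zmat3, an RNA-binding zinc finger protein (1.10, SE 0.11). Pmaip1 went from 58.1 ± 5.02 to 164 ± 30.6, Perp from 67.5 ± 7.92 to 167 ± 28.6 and Zmat3 from 508 ± 58.3 to 1088 ± 119 (SD, n = 3 per genotype). All 3 probe sets of Ccng1 rose, by 2.44 to 2.52, whereas the second, dimmer probe set of Trp53inp1 differed by 0.69 and did not pass (adjusted p = 0.801). All 5 genes passed over all probe sets tested (limma adjusted p from 5.71e-05 to 0.0321) and 5 adjusted over the list alone. These genes were chosen on the same embryos, so neither their count nor their set test (camera adjusted p = 3.82e-16) is independent evidence of the direction. With an estimated correlation between genes the camera adjusted p was 0.113. The number of these genes that passed fell to 2 without wild-type embryo 1, to 3 without heterozygous embryo 1 or 2 or wild-type embryo 2 or 3, and to 0 without the intensity trend. The median difference over the 5 genes was 1.60 on the first scan day and 1.16 on the second, and 1.51 between female and 1.43 between male embryos.

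A separate list of 48 other p53 targets, of which 42 were tested, was higher in heterozygotes as a group, with 37 positive and 5 negative differences and a median log2 difference of 0.40. Over all probe sets 7 members rose: Cdkn1a (log2 3.13, SE 0.24), Eda2r (2.62, SE 0.23), Dcxr, a dicarbonyl and xylulose reductase (1.84, SE 0.24), the thiamine transporter gene Slc19a2 (1.66, SE 0.16, and 2.00 on a dimmer probe set), the adenylate kinase gene Ak1 (1.24, SE 0.16), Psrc1, a spindle-associated protein gene (0.84, SE 0.11), and Phlda3, a pleckstrin homology domain protein gene named here after its values were seen (1.28, SE 0.17). The other 35 members did not pass over all probe sets. Adjusted over the list alone, 19 were higher and 0 lower. Mdm2, the gene of the ubiquitin ligase that degrades p53, and Bbc3, the gene of the pro-apoptotic protein Puma, were also picked out after their values were seen. Mdm2 was at 252 ± 13.3 and 336 ± 51.6, with a limma adjusted p of 0.692 over all probe sets and 0.0217 over the list, and Bbc3 differed by 0.47 (SE 0.19), with adjusted p of 0.781 and 0.0717. The camera adjusted p of the list was 1.52e-22 with the preset correlation, and the adjusted p was 0.113 with an estimated correlation. The count of 7 became 3 when any 1 array other than heterozygous embryo 3 was left out and 0 without the intensity trend. The median difference was 0.44 on the first scan day and 0.34 on the second, and 0.34 between female and 0.42 between male embryos.

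**Figure D2:**
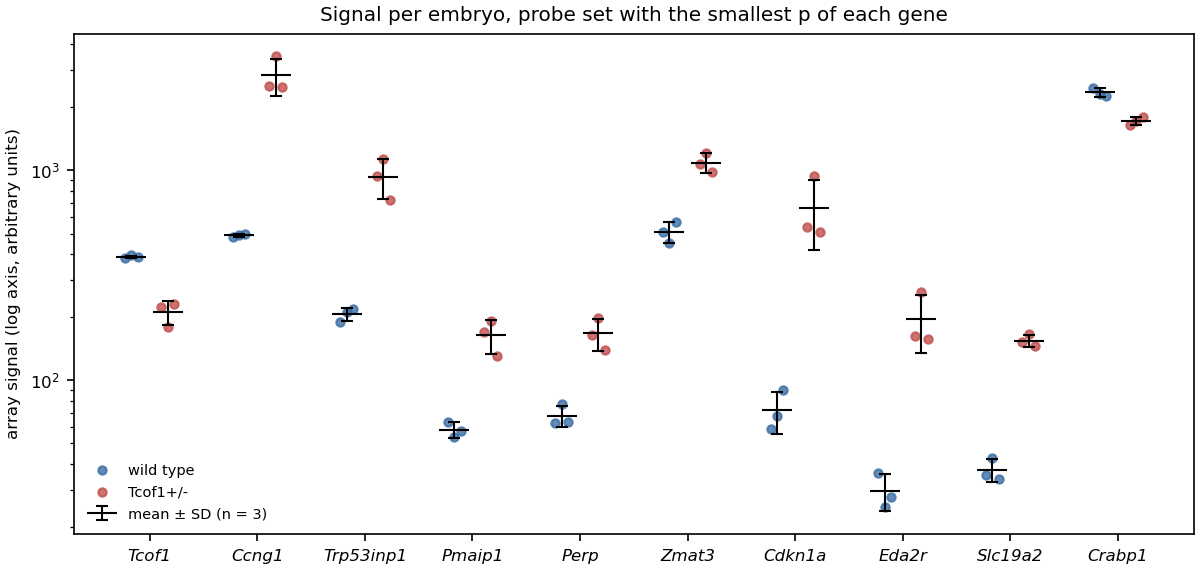
Array signal (logarithmic axis, arbitrary units) of 10 genes in each embryo, wild type in blue and Tcof1 heterozygous in red, with black bars for the mean ± SD of 3 embryos. Tcof1 is lower in every heterozygote, 8 p53 targets from Ccng1 to Slc19a2 are higher in every heterozygote, and Crabp1 at the right, which did not pass the test, lies at 2356 in wild types and 1724 in heterozygotes.

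Outside the p53 lists, 3 named genes rose. Ddit4l, an inhibitor of mTOR signalling, rose 3.34-fold on its brighter probe set, from 52.2 ± 6.56 to 181 ± 41.8 (limma adjusted p = 0.0113), and a second probe set rose by 1.67 on the log2 scale. Another, dimmer probe set of Ddit4l differed by 2.15 and did not pass (adjusted p = 0.0882). Lrrfip1, a nucleic acid binding protein gene, rose 1.53-fold, from 1011 ± 27.1 to 1546 ± 110 (adjusted p = 0.0236). A second probe set of Lrrfip1 differed by 0.63 (adjusted p = 0.391) and the dimmest by -0.04 (adjusted p = 0.971), and neither passed. Ifrd1, a transcriptional coregulator gene named after its values were seen, rose by 0.64 (SE 0.09, adjusted p = 0.0331).

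No named gene other than Tcof1 passed in the lower direction, and the 11 lower genes with the next smallest p had limma adjusted p from 0.0640 to 0.211. The major histocompatibility class I gene H2-K1 was at 0.58 of the wild-type level (log2 -0.78, SE 0.11, adjusted p = 0.0640), with 3 of its 4 probe sets negative and 1 positive at 0.14. Crabp1, a cytoplasmic retinoic acid binding protein gene of neural crest and hindbrain, was at 2356 ± 113 in wild types and 1724 ± 74.3 in heterozygotes (log2 -0.45, SE 0.07, adjusted p = 0.0662). Aldh18a1 (-0.70) and Ildr2 (-0.58) followed, with adjusted p of 0.0791 and 0.0797. The remaining genes of this group were Spg20 (-0.51), Pik3cd (-0.41), Isoc1 (-0.68), Ift74 (-0.50), Timp2 (-0.59), Armc8 (-0.61) and Mapre1 (-1.01). Crabp1 and Ift74 had 1 tested probe set each. For the 8 genes other than H2-K1 with several tested probe sets, the others lay nearer 0 or were positive. They differed by -0.40 to -0.05 for Aldh18a1, -0.23 to -0.04 for Ildr2, -0.17 to -0.14 for Spg20 and -0.39 to -0.16 for Timp2. For Armc8 they differed by -0.25 to 0.25, for Isoc1 by -0.03 to 0.37, for Mapre1 by 0.03 to 0.39 and for Pik3cd by -0.17. The signals for Pik3cd were far apart, at 2957 to 4313 on the probe set named above and 15.8 to 32.7 on the other tested one. The remaining probe sets of Pik3cd were too dim to be tested.

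Genes of the brain and neural tube were lower in heterozygotes as a group, although none passed singly over all probe sets. Of 31 tested members 27 were negative and 4 positive, with a median log2 difference of -0.36. The forebrain and eye field transcription factor genes Lhx2 (56.2 ± 9.07 against 27.9 ± 3.57) and Pax6 (183 ± 24.9 against 121 ± 6.75) had the smallest p, with log2 differences of -0.96 and -0.58 and limma adjusted p of 0.457 and 0.492. Adjusted over the list alone, 5 were lower and 0 higher: Lhx2, Pax6, and, named after their values were seen, the neural progenitor gene Sox1 (-0.63), the forebrain and midbrain gene Otx2 (-0.53) and the Wnt antagonist gene Sfrp1 (-0.36). The camera adjusted p was 2.28e-08, and the adjusted p was 0.113 with an estimated correlation. The median over the list was -0.39, -0.44 and -0.21 in heterozygous embryos 1, 2 and 3 relative to the wild-type mean. Within the first scan day the median difference was -0.52, and within the second -0.13; it was -0.43 between female and -0.32 between male embryos. The 3 prime to 5 prime log2 difference of the Gapdh control, a measure of RNA quality, was larger in wild types, at 0.91, than in heterozygotes, at 0.76. Its exact permutation p was 0.1, the smallest possible, and 0.467 when adjusted over the array measures compared.

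Neural crest genes were lower as a group by a smaller amount, with 24 of 30 tested members negative, 6 positive and a median of -0.16. Crabp1 and Tfap2b, the gene of the transcription factor AP-2 beta (159 ± 16.7 against 101 ± 18.8, log2 -0.66), were the 2 members lower when adjusted over the list alone, and none passed over all probe sets. The camera adjusted p was 0.00243, and the adjusted p was 0.450 with an estimated correlation. The median over the list was -0.16, -0.16 and -0.13 in heterozygous embryos 1, 2 and 3 relative to the wild-type mean, with 23, 20 and 21 of 30 members below it. The median difference was -0.20 on the first scan day and 0.04 on the second, which held 1 embryo of each genotype, and -0.21 between female and -0.10 between male embryos. The Gapdh 3 prime to 5 prime log2 difference was 0.91 in wild types and 0.76 in heterozygotes, as beside the brain list.

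Primitive erythroid genes were lower on average, with 13 of 13 tested members negative and a median of -0.93, and were lowest in heterozygous embryo 1. The median deviation of the list from its mean over all embryos was -1.27, -0.37 and 0.61 in heterozygous embryos 1, 2 and 3, and 0.46, 1.10 and 0.11 in wild-type embryos 1, 2 and 3. Hbb-bh1, an embryonic beta globin, gave a signal of 146 in heterozygous embryo 1 against 2565 to 6187 in the other 5 embryos, and Hba-x, an embryonic alpha globin, gave 24.1 against 481 to 1664; both globins were chosen after their values were seen. Alas2, of erythroid haem synthesis (-1.40, SE 0.61), and the erythroid transcription factor gene Klf1 (-0.93, SE 0.41) had limma adjusted p of 0.793. No member passed over all probe sets or over the list alone. The camera adjusted p was 4.44e-04, the adjusted p was 0.534 with an estimated correlation, and it was 0.111 without heterozygous embryo 1. The median was -1.72 on the first scan day and 0.40 on the second, and -2.02 between female and 0.02 between male embryos.

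Genes of cholesterol synthesis were lower as a group, with 20 of 20 tested members negative and a median of -0.25. The sterol desaturase gene Sc5d (185 ± 2.92 against 148 ± 7.73, log2 -0.31) and the mevalonate pathway gene Mvd (log2 -0.37, SE 0.15) had limma adjusted p of 0.754 and 0.781. No member passed over all probe sets or over the list alone. The camera adjusted p was 1.40e-04, the adjusted p was 0.534 with an estimated correlation, and it was 0.0771 without heterozygous embryo 1. The median was -0.36 on the first scan day and 0.13 on the second, and -0.50 between female and 0.01 between male embryos.

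Higher as groups were the lists of heart, endothelium and surface ectoderm genes. Of 28 tested heart genes 22 were positive, with a median of 0.12. Tbx20, a cardiac transcription factor gene, had the smallest p (log2 0.52, SE 0.09, limma adjusted p = 0.162) and was the 1 member higher when adjusted over the list alone. The atrial myosin light chain gene Myl7 differed by 0.27. The heart list had a camera adjusted p of 0.00254, lost with an estimated correlation (adjusted p = 0.534), without heterozygous embryo 2 (0.359), without wild-type embryo 3 (0.0703) and on the first scan day alone (0.119). Its median was 0.07 on the first scan day and 0.23 on the second, and -0.07 between female and 0.26 between male embryos.

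Of 22 tested endothelial genes 16 were positive, with a median of 0.11. The ETS factor genes Erg (0.44) and Fli1 (0.43) had limma adjusted p of 0.778 and 0.784, and none passed over all probe sets or over the list alone. The endothelial list had a camera adjusted p of 0.0284, lost with an estimated correlation (adjusted p = 0.534), with the mean of all probe sets per gene (0.110), with Xist signal as a covariate (0.0778) and on the first scan day alone (0.543). It was also lost without wild-type embryo 1 (0.281) or 3 (0.147) and without heterozygous embryo 2 (0.135) or 3 (0.165). Its median was 0.06 on the first scan day and 0.21 on the second, and -0.02 between female and 0.20 between male embryos. Of 18 tested surface ectoderm genes 12 were positive, with a median of 0.13. Perp, which is also a p53 target, was the 1 member that rose, over all probe sets and over the list alone, and the desmosomal gene Dsp differed by 0.27 (adjusted p = 0.774). The surface ectoderm list had a camera adjusted p of 0.00671, lost with an estimated correlation (adjusted p = 0.450), without heterozygous embryo 1 (0.130) and without wild-type embryo 3 (0.0574). Its median was 0.17 on the first scan day and 0.10 on the second, and 0.23 between female and 0.07 between male embryos.

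**Figure D3:**
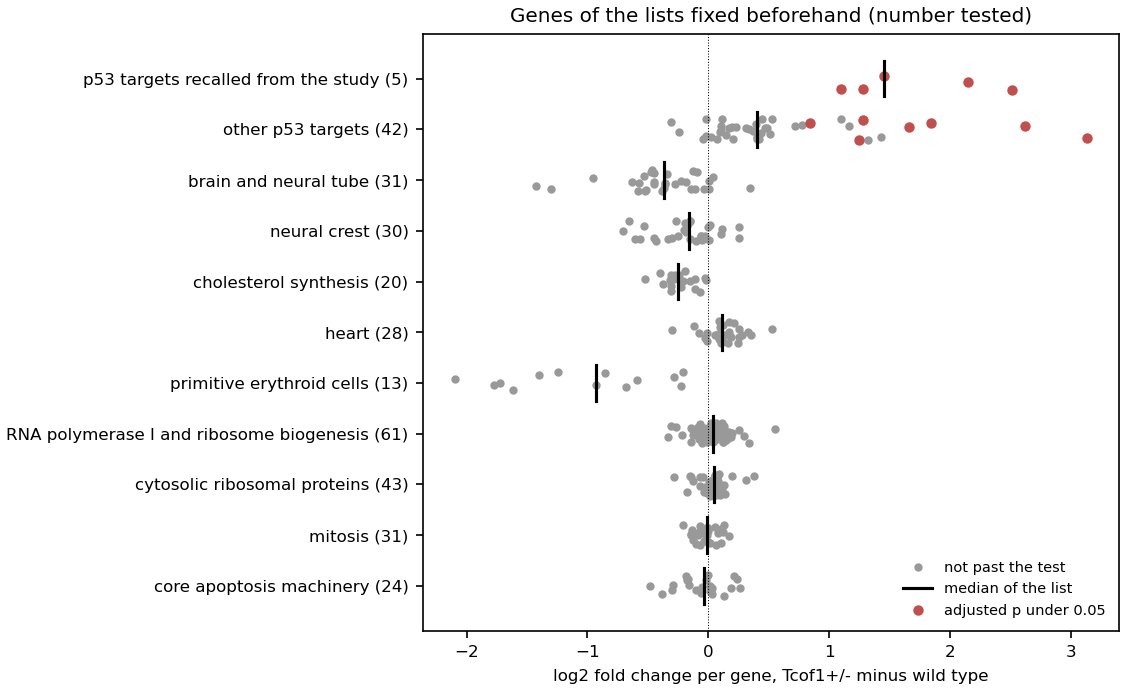
Each point is the log2 fold change of 1 gene, heterozygous over wild type, in 11 of the gene lists chosen before the data were examined, with the number of genes tested in brackets and a black bar at the median of the list. Red points passed the test over all probe sets. Both p53 lists lie to the right (medians 1.45 and 0.40), and brain and neural tube (-0.36), cholesterol synthesis (-0.25) and erythroid genes (-0.93) lie to the left.

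The lists closest to the known function of treacle did not pass. They hold transcript levels of genes and do not measure ribosomal RNA synthesis itself. Of 61 tested genes of RNA polymerase I and ribosome biogenesis 34 were positive and 27 negative (median 0.03, camera adjusted p = 0.238), with Utp20 at 0.29 and Nol6 at 0.55 having the smallest p. Of the 79 cytosolic ribosomal protein genes listed, 43 were tested and 32 were positive (median 0.05, camera adjusted p = 0.0934). Rps9 was at 0.14 and Fau at -0.15, and the list passed without wild-type embryo 2 (0.0384). Core apoptosis genes had 10 positive and 14 negative members (median -0.04, adjusted p = 0.486), with Bad at -0.48 and Cycs at 0.21. DNA repair genes had 11 positive and 17 negative members (median -0.05, adjusted p = 0.672), with Brca2 at -0.37 and Rad51c at -0.38. DNA replication genes were negative in 25 of 31 (median -0.05, adjusted p = 0.0672), with Uhrf1 at -0.28 and Fen1 at -0.29; the list passed without heterozygous embryo 2 (0.0263) and with quantile normalization (0.0350). Mitosis genes were negative in 21 of 31 (median -0.01, adjusted p = 0.711), with Ccnb2 at -0.21 and Cenpa at -0.14.

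Other lists of tissues did not pass camera. The adjusted p was 0.672 for cranial placodes and pharyngeal arches (16 tested, median 0.03; Sox21 at -0.39, Fgf15 at 0.33), 0.413 for paraxial mesoderm and somites (28 tested, median -0.01; Lfng at -2.01, Foxc1 at -0.42) and 0.301 for Hox genes (22 tested, median 0.02; Hoxd1 at 0.27, Hoxb1 at 0.28). It was 0.535 for gut endoderm and notochord (17 tested, median 0.15; Otx2 at -0.53, Nog at -1.45), whose median was positive and mean negative at -0.04. It was 0.535 for visceral endoderm and yolk sac (29 tested, median 0.05; Habp2 at -0.85, F5 at 0.44), 0.0711 for trophoblast (6 tested, median 0.23; Rhox9 at 0.82, Plac1 at 0.29) and 0.880 for decidua and maternal leukocytes (9 tested, median 0.05; Laptm5 at -0.56, Pgr at 0.35), of which the last had a positive median and a negative test direction. None of these members passed over all probe sets. In heterozygous embryos 1, 2 and 3, Lfng gave 6.64, 7.80 and 12.6 and Nog gave 14.6, 10.6 and 2.04. These signals lay near or below the brightest unspiked bacterial control (8.55 to 13.5), so the sizes of both differences are uncertain. Without heterozygous embryo 1 the Hox list passed (0.00208), and without heterozygous embryo 2 the yolk sac list passed (1.74e-05). The trophoblast list passed with equal array medians (0.0405), with the replicate number as a block (0.0121) and with scan day as a block (0.0452).

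Stress, signalling and metabolic lists also did not pass camera. The stress response gene Sesn2, of the integrated stress and unfolded protein response list and also of the second p53 list, was at 77.5 ± 14.3 and 179 ± 50.8 (log2 1.16, limma adjusted p = 0.262) and was the 1 member higher when adjusted over that stress list alone. That list had an adjusted p of 0.869 (24 tested, median -0.01; Hsp90b1 at 0.10), with a positive test direction. The adjusted p was 0.797 for heat shock (15 tested, median 0.00; Hsp90aa1 at 0.15, Bag3 at -0.37) and 0.816 for immediate early genes (21 tested, median -0.03 and mean 0.02; Dusp1 at -0.40, Fos at 0.58). It was 0.115 for hypoxia and glycolysis (29 tested, median -0.06; Tpi1 at -0.14, Vegfa at -0.42), which passed without heterozygous embryo 2 (0.0165) and with quantile normalization (0.0385). It was 0.486 for the mitochondrial respiratory chain (42 tested, median -0.00, with a positive test direction; Atp5b at 0.18, Uqcrq at -0.29). For targets of Wnt, Fgf, Shh, Bmp and retinoic acid signalling it was 0.413 (32 tested, median 0.02; Id2 at 0.32, Smad6 at 0.40). For genes near Tcof1 on its chromosome it was 0.531 (14 tested, median 0.08 and mean -0.01; Rps14 at 0.10 and Cdx1 at a mean signal of 88.3 in wild types and 50.2 in heterozygotes).

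The embryos differed in sex. Xist, which is transcribed from the inactive X chromosome, exceeded the Y-linked gene Eif2s3y in wild-type embryos 1 and 2 and heterozygous embryo 1, with Xist signals of 1520 to 2358, and the order was the opposite in the other 3, with Eif2s3y at 491 to 555. Wild types thus had 2 embryos of the first kind and 1 of the second, and heterozygotes 1 and 2, so that each comparison within a sex has 1 embryo of 1 genotype. The list of Xist and Y-linked genes had a camera adjusted p of 0.486 (4 tested, median 1.61; Uty at 1.54, Kdm5d at 2.04). The median size of the 22 differences between genotypes was 93.9% of the pooled difference between female and 103% between male embryos. Because the 22 were called on these same embryos, their sizes within a sex were limited by the call and are no separate evidence. With Xist signal as a covariate, a setting chosen after seeing the data, 9 of the 22 passed. The 22 differences were then 93.5% to 103% of their size without it, with a median standard error of 0.18 in place of 0.17 and 3 residual degrees of freedom in place of 4.

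The 3 prime to 5 prime log2 difference of the Gapdh control, a measure of RNA quality, was 0.91 ± 0.11 in wild types and 0.76 ± 0.07 in heterozygotes, without overlap (SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays can give), and so stood beside every gene and list that differed between the genotypes. For beta-actin it was 0.80 ± 0.05 and 0.74 ± 0.07 (exact permutation p = 0.2). Adjusted over the array measures compared, the permutation p was 0.467 for Gapdh and for beta-actin. The hybridisation controls averaged 8.99 ± 0.19 and 9.32 ± 0.31 on the log2 scale (exact permutation p = 0.3).

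**Figure D4:**
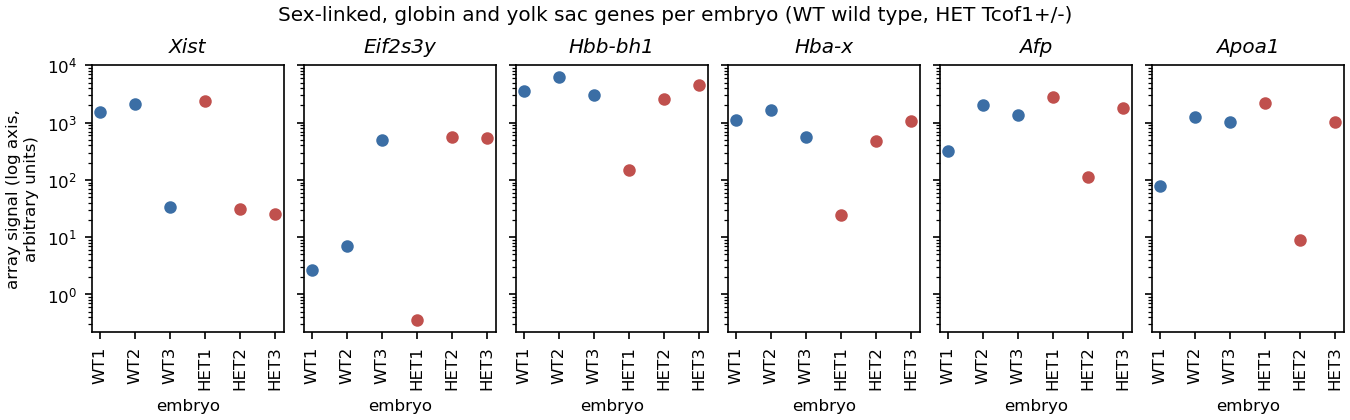
Array signal (logarithmic axis, arbitrary units) of 6 marker genes in each embryo, wild type (WT) in blue and heterozygous (HET) in red. Xist and Eif2s3y part the embryos by sex, Hbb-bh1 and Hba-x are lowest in heterozygous embryo 1 (146 and 24.1), and the yolk sac genes Afp and Apoa1, chosen like the globins after their values were seen, are lowest in heterozygous embryo 2 (113 and 8.79).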

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

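All 22 changed probe sets kept their direction under the 19 alternatives that refit them, but in most of these the direction could not change. Where arrays were left out or weighted, or the pseudocount was changed, it follows from their separation of the genotypes. Both other filters, the prior without the trend, sex-linked genes left out and both blocks leave every fold as it was. The alternatives with Xist signal as a covariate and with the first scan day alone were chosen after seeing the data. Array signals near 13, the range of the brightest unspiked bacterial control (8.55 to 13.5), limit what dim genes can show. Where a call was lost, the cause was not tested, except that fits with fewer arrays or with added terms have fewer residual degrees of freedom.

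Without the intensity trend in the variance prior, 0 probe sets passed (0 higher and 0 lower), 1571 had an unadjusted p under 0.05, Tcof1 stayed at -0.88 (adjusted p = 0.413; range over the alternatives 0.0233 to 0.413), and 0 members of either p53 list passed. Deviations from the genotype mean correlated at -0.079, -0.105 and -0.024 between embryos of the same replicate number. These values show no large shift shared by such embryos, but not whether they came from the same litter. With the replicate block 10 probe sets passed (10 higher, 0 lower), Tcof1 stayed at -0.88 (adjusted p = 0.182), and 2 and 3 members of the p53 lists passed. With scan day as a block 14 passed, 0 of them lower, and Tcof1 stayed at -0.88 (adjusted p = 0.0906). The fold of Tcof1 is the same by design without the trend and with either block. With Xist signal as a covariate 9 passed (9 higher, 0 lower), Tcof1 was at -0.86 (adjusted p = 0.143), and 3 and 3 members of the p53 lists passed. The first scan day alone gave 12 (10 higher, 2 lower), Tcof1 at -0.95 (adjusted p = 0.217), and 3 and 4 members. Quantile normalization and the filter at 60% each gave 2 lower probe sets. With an estimated correlation 0 other lists passed camera, and both p53 lists had an adjusted p of 0.113.

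Leaving out 1 array gave 8 to 20 changed probe sets (8 to 18 higher, 0 to 2 lower), with 8 without wild-type embryo 1, 11 without wild-type embryo 2 or 3, and 12 without heterozygous embryo 2. Tcof1 ranged from -0.95 to -0.77 and passed in 0 of 6 such fits. Members that passed numbered 2 to 5 in the first p53 list and 3 to 6 in the second, whose camera adjusted p ranged from 4.30e-16 to 8.29e-13 and from 5.98e-22 to 4.94e-18. Other lists past camera numbered 4 to 8, with 4 without wild-type embryo 3.

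Of 2146 values of single genes and lists recomputed, 2008 kept direction and side of the threshold, 95 lost the threshold, 12 passed newly and 31 changed direction. The lists that changed direction had not passed as described and did not pass in the settings that turned them; the yolk sac list passed, in its described direction, without heterozygous embryo 2. They were heat shock with quantile normalization (adjusted p = 0.888) and with the mean of all probe sets (0.820); immediate early genes with the replicate block (0.952), scan day (0.956), Xist (0.859) and the first day (0.668); decidua and maternal leukocytes with the mean of probe sets (0.740), Xist (0.860) and the first day (0.767); and paraxial mesoderm (0.668), mitosis (0.668), hypoxia (0.668) and genes near Tcof1 (0.842) on the first day. With 1 array left out, lists that changed direction at least once had adjusted p from 1.74e-05 to 0.750 (yolk sac), 0.635 to 0.933 (decidua), 0.767 to 0.855 (integrated stress), 0.413 to 0.905 (immediate early), 0.567 to 0.873 (DNA repair), 0.567 to 0.954 (heat shock), 0.263 to 0.954 (placodes), 0.332 to 0.994 (mitosis), 0.187 to 0.933 (respiratory chain) and 0.346 to 0.933 (genes near Tcof1).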

Other observations

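Yolk sac and visceral endoderm genes differed more between embryos than between genotypes. Afp, a secreted protein of the yolk sac endoderm, and Apoa1, an apolipoprotein gene, were chosen after their values were seen. Afp gave 321, 2050 and 1371 in wild-type embryos 1, 2 and 3 and 2770, 113 and 1792 in heterozygous embryos 1, 2 and 3. Apoa1 gave 78.9, 1255 and 1026 against 2166, 8.79 and 1027. The median deviation of the 29 tested yolk sac genes from their mean over all embryos was -1.28, 0.72 and 0.59 in wild types and 1.45, -2.10 and 0.65 in heterozygotes. Among the 21 probe sets called higher, heterozygous embryo 2 had the highest of the 3 heterozygous signals in 20, and its Tcof1 signal (179) was the lowest of the 6.

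The tests of sex, scan day, RNA quality, tissue outside the embryo and array scale were chosen after the results were seen; the others were chosen before. An earlier form of the tissue test that rested on 1 array, and a test of other yolk sac genes that grouped arrays by their Afp signal, had also been run and were set aside as unsound, as were tests of sex and scan day on the changed probe sets themselves, whose values within any subset were limited by how they were called, and a test of array scale that the authors' scaling had fixed. A test that picked 22 probe sets in 1 sex and measured them in the other (8 of 22 in the same direction from females to males, 19 of 22 from males to females) was set aside because each sex has 1 embryo of 1 genotype, and 4 of the 22 picked in females were among the changed probe sets.

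For the changed probe sets between genotypes, the 10 splits of the 6 arrays are too few for a share under 0.05; 1 of them, the real one, gave as many as 22 calls, and the highest other, 11, was the split by sex, in which 6 of the 7 calls with a gene symbol were Xist or Y-linked and 4 had none. Each scan day held equal numbers of both genotypes, so a shift between days could not by itself part them. Of 22 probe sets picked by the smallest limma p on the arrays of the first scan day alone, 20 went the same way on the second. The median was 71.5% of the first-day difference (quartiles 54.1% and 88.5%), which also argues against scan day, with 1 embryo of each genotype on the second. For the list of other p53 targets, fixed beforehand, a fit over the 6 arrays with sex as a term gave a genotype coefficient of 0.42 for the median of the list and a sex coefficient of 0.02 (residual SD 0.10, 3 residual degrees of freedom), which argues against unequal sex numbers as the cause for these genes. For changed genes outside the p53 lists sex stays open, since calling them limited how far embryos of 1 genotype could differ. Fluidics module parted the genotypes (1 or 3 for wild types, 2 or 4 for heterozygotes) and cannot be told apart from genotype. Hypothesis: the rise of p53 targets may belong to the genotype, with stage, fluidics module and the litter of each embryo left open.

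The lower brain and neural tube genes may reflect fewer or altered neural cells in heterozygotes, or a technical difference. More yolk sac or other tissue outside the embryo was weighed against 130 genes of other tissues of the embryo. The brain list lay below these by a group difference of -0.47, against a pooled SD of 0.10 between arrays. The 130 genes include the heart, endothelium and surface ectoderm lists, already seen to be higher, and some may also be expressed outside the embryo. The comparison therefore cannot decide, and such tissue stays open. RNA quality cannot be told apart from genotype, because the Gapdh 3 prime to 5 prime difference separated the genotypes without overlap (exact permutation p = 0.1) while that of beta-actin did not (exact permutation p = 0.2). Fewer neural cells and lower expression per cell stay open.

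The low signals of 3 of the 4 tested globins in heterozygous embryo 1 were weighed as a property of the array or of the embryo. The exception was Hba-a2, named after its values were seen, at 0.34 on the log2 scale above the median of the other 5 arrays. A factor on the whole array would move all probe sets alike. The median of the 4 globins lay at -4.98 relative to that of all tested probe sets there, below the central 95% of them (-0.87 to 0.79). The globins were examined because they had been seen to be low on this array, so that outcome was fixed and does not test such a factor. It describes how far the globins lay from the other probe sets. The 9 other erythroid genes were all lower there than the median of the other 5 arrays, with a median of -1.31 and 6 of 9 lower by more than 1, which is consistent with fewer erythroid cells in the RNA of that embryo. Whether these were lost in dissection or fewer in the embryo was not tested.

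A further hypothesis was that alleles of another strain linked to Tcof1 may add differences near the gene. Of the 3 called genes outside the p53 lists and Tcof1, 0 lay on the chromosome of Tcof1. Among the 100 tested genes nearest to Tcof1, 6 had an unadjusted p under 0.05, against 6.88% of all other genes (one-sided Fisher exact p = 0.692; upper 95% bound of the share 12.6%), and 1 of the 6 was the p53 target Pmaip1, 33 tested genes away. The 3 called genes are too few to weigh linked alleles. The share near Tcof1 showed no excess, but its bound leaves room for up to 12.6%. It also rests on 1 probe set per gene, that with the highest mean. Linked alleles therefore stay open for single genes such as Isoc1, 9 tested genes away, whose tested probe sets differed by -0.68, -0.03, 0.13 and 0.37.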
